A study of Mus musculus with 16 samples.

How the data were processed

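RNA was sequenced from the colon of adult ICR mice, an outbred stock. The animals had been born by vaginal delivery (VD) or by cesarean section (CS), and drank either normal water or water with 3% dextran sulfate sodium (DSS), a detergent-like polymer that injures the colon lining, for 8 days. The 4 groups are named CON_VD, CON_CS, DSS_VD and DSS_CS, with 4 libraries each and 16 in all. Groups and replicate numbers were taken from the labels. The labels do not say whether each library came from a separate mouse, nor which litters the mice came from, so p-values measure only the spread between these samples.

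The values are FPKM (fragments mapped to a gene, scaled by gene length and by library depth) that the authors deposited as 1 table of 39328 genes by 16 libraries. Adapter trimming with cutadapt, read quality control with FastQC and the genome build GRCm38 are named in the submitters' processing notes, without versions. The aligner, the quantifier and the annotation are not given in the sources used here. Total RNA was extracted with Trizol, per the labels' protocols. Whether the libraries kept strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and values of near-identical gene copies depend on how the authors assigned shared reads.

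No read counts were used here, and the depth of each library is unknown. Among 16959 genes with every value under 0.3 FPKM, the ratios between libraries did not fall on steps of whole reads: in each of the 120 pairs of libraries at most 0.978% of the log2 ratios, rounded to 0.01, shared 1 value. FPKM sums per library ranged from 280135 to 343423, and 24150 to 26328 genes were above 0. An FPKM of 0 can be a failed estimate, so genes are described as listed at 0.

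Gene symbols came from a reference table of gene names, and positions from GENCODE M21, which is on GRCm38 like the build in the processing notes. Of the 39328 genes, 3988 were above 0 in no library; 39181 gene identifiers matched a symbol and 147 did not. Where a symbol had several identifiers, the identifier with the highest mean FPKM was used. Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the variance prior. Fold changes are on this scale, which understates changes of low genes. A gene was tested when at least 4 of the fitted libraries had an FPKM of at least 1. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Each comparison of 2 groups was fitted on its own 8 libraries, and the interaction of delivery and DSS on all 16.

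A collection of 29 gene lists for colon cell types, immunity, injury and possible neighbouring tissues was fixed before the data were examined, together with the tests, the rule for named genes and most alternatives. Lists with at least 4 tested members were compared with all other genes by camera, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. No list in any of the 5 comparisons stayed under the threshold when camera estimated the correlation from the data; the p-values of that setting are given beside each list. List scores per library are means of log2(FPKM + 1).

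Named genes were chosen by a rule. Its first part takes up to 7 genes with the largest rise and 7 with the largest fall among genes under the threshold whose group ranges do not overlap and whose mean FPKM reaches 5 in the higher group. Immunoglobulin and T cell receptor segments, predicted genes and genes listed at 0 in a library of the higher group were left out. Its second part takes the 3 members of smallest p from up to 8 lists. Its last part takes genes of type 3 and type 1 immunity, among them Il22, Il17a, Il23r, Ifng and Tbx21, because the series title names group 3 innate lymphoid cells (ILC3). Some genes that the rule and the tests take are not reported here. Single values and scores were compared with exact two-sided permutation tests in scipy 1.17.1, for which the smallest p with 4 against 4 libraries is 0.0286. The difference between the DSS responses of the delivery groups in the pan-epithelial score was tested over all 4900 exchanges of delivery labels within DSS and within water. This test and those of the pan-epithelial score between DSS and water were added after seeing the data. Such exchanges of delivery labels assume no delivery difference under DSS or under water, so they do not test the interaction alone. Figures were drawn with matplotlib 3.10.9.

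The fits were tested on simulated data with 200 changed genes per comparison. Of genes changed by a log2 of 1, 67% were recovered for CS against VD under DSS, among 14313 simulated genes. For CS against VD under water 82% were recovered among 13275, for DSS in VD mice 64% among 13933, for DSS in CS mice 73% among 14372, and for the interaction 66% among 15233. False calls numbered 10, 6, 10, 11 and 9 in the same order. Noise was drawn separately for each gene, with a spread pooled over the groups. Variation shared between genes was not simulated, so recovery and false calls in the real data may differ.

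Alternatives tried were a pseudocount of 0.1, no filter, a filter of mean FPKM of at least 5, rescaling each library to a fixed sum (TPM scale), median-of-ratios scaling, no variance trend, library weights, a fold threshold, a replicate block, 1 fit on all 4 groups and leaving out each library. Removing libraries that carried prostate or adipose genes was chosen after seeing the data. No library was left out of the main tests.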

Results

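Colon transcriptomes were compared between mice born vaginally (VD) and mice born by cesarean section (CS), each on normal water or on 3% DSS for 8 days, with 4 libraries per group. The title of the series names colitis susceptibility after cesarean birth and ILC3, lymphoid cells of barrier tissues that make interleukin-22. Values are deposited FPKM, and read depth is unknown. Pearson correlations of log2(FPKM + 1) between libraries of a group ranged from 0.938 to 0.980, and the first principal component held 68.1% of the variance. Correlations between delivery groups overlapped this range, with 0.939 to 0.968 between CON_VD and CON_CS libraries. DSS_CS replicate 1 correlated at 0.954 with DSS_VD replicate 4, and at 0.938 to 0.947 with the other DSS_CS libraries. Values are means ± SD over 4 libraries, and log2 fold changes are given ± SE.

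The first question was how CS and VD mice differed under DSS. Of goblet cell and absorptive colonocyte genes, 8 of 13 and 8 of 15 were lower in DSS_CS than in DSS_VD, and 10 of 14 matrix genes were higher. Slc26a3, the chloride-bicarbonate exchanger of surface colonocytes (ENSMUSG00000001225, chromosome 12, 31390871 to 31473917, GRCm38), was at 12.7 ± 5.25 FPKM in DSS_VD and 1.22 ± 1.05 in DSS_CS, and fell by 2.64 ± 0.41 on the log2 scale (adjusted p = 0.0309). Ccl4, a chemokine of myeloid and lymphoid cells (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), was at 4.45 ± 1.40 and 33.1 ± 15.3 FPKM, a log2 rise of 2.58 ± 0.33 (adjusted p = 0.0225). In all, 1923 of 14313 tested genes passed the threshold, 1130 higher and 793 lower in DSS_CS. This balance depended on the setting, with 854 higher and 855 lower under median-of-ratios scaling, and 184 higher and 427 lower where a change of at least 2-fold was required.

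Of 13 measured goblet cell and mucus genes, 8 were lower in DSS_CS and none higher (12 lower adjusted over the list alone; camera adjusted p = 2.18e-08, adjusted p = 0.484 with an estimated correlation). Muc13, a membrane mucin, went from 635 ± 229 FPKM in DSS_VD to 172 ± 86.6 in DSS_CS. The mucus protein Fcgbp went from 77.4 ± 32.5 to 21.9 ± 7.29, Spink4 from 137 ± 74.3 to 27.3 ± 16.8 and Retnlb, a secreted antibacterial protein of goblet cells, from 279 ± 212 to 37.6 ± 24.4. Absorptive colonocyte genes numbered 8 lower of 15, with none higher (11 lower adjusted over the list alone; camera adjusted p = 1.04e-07, adjusted p = 0.484 with an estimated correlation). They included the water channels Aqp8 (117 ± 125 against 10.4 ± 5.36) and Aqp4 (24.6 ± 8.65 against 5.50 ± 4.51), the carbonic anhydrase Car4 (307 ± 248 against 34.3 ± 24.0) and the sodium channel subunit Scnn1g (log2 -0.93 ± 0.20, adjusted p = 0.0331). Among 16 junction genes 6 were lower, among them the claudins Cldn8 (log2 -1.94 ± 0.39) and Cldn3 (-1.56 ± 0.39) and the tight junction protein Ocln (-1.17 ± 0.30). The list had 12 lower adjusted over the list alone (camera adjusted p = 1.5e-06, adjusted p = 0.484 with an estimated correlation). Beside these groups, the general epithelial gene Epcam ranged from 317 to 716 FPKM in DSS_VD and from 91.9 to 312 in DSS_CS. The mean of 10 pan-epithelial genes was lower by a log2 of -1.20 in DSS_CS, with an exact permutation p = 0.0857. Ces2e, an intestinal carboxylesterase, and the protease gene Prss30 were also among the largest falls, by 2.95 ± 0.48 and 2.61 ± 0.61 (adjusted p = 0.0313 and 0.0361).

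Genes of the IL-22-responsive and antimicrobial epithelium went mostly the same way, with 10 of 16 lower and 1 higher in DSS_CS (10 and 3 adjusted over the list alone; camera adjusted p = 3.52e-04, adjusted p = 0.484 with an estimated correlation). Dmbt1, a secreted scavenger receptor of the mucosa, fell by 2.51 ± 0.36, from 637 ± 188 to 117 ± 57.7 FPKM (adjusted p = 0.0299). Pigr, the receptor that carries IgA across the epithelium, went from 297 ± 98.0 to 58.3 ± 31.6. Lbp, the lipopolysaccharide-binding protein, was the 1 member higher over all genes, from 14.0 ± 4.40 to 40.8 ± 2.12 (log2 1.52 ± 0.20, adjusted p = 0.0225). The other 5 members, Saa3 among them, did not pass over all genes. The mean log2 difference of the list was -1.05, beside -1.20 for the pan-epithelial genes. Whether the list differed beyond a smaller share of epithelial RNA was not tested.

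Among genes of type 3 and type 1 immunity, Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047) was at 4.87 ± 3.02 FPKM in DSS_VD and 1.68 ± 0.455 in DSS_CS. Its ranges did not overlap, 2.67 to 9.27 against 1.11 to 2.18 (exact permutation p = 0.0286, the smallest possible), while its adjusted p over all genes was 0.0577. Group ranges were also apart for 3216 of the 14313 tested genes (22.5%), so this separation was not particular to Il22. Il17a, Il23r, Ifng and Tbx21 were below the filter, with group means of at most 0.699 FPKM. Members of the ILC3 and type 3 list went both ways, with 6 of 12 above 0 and 6 below in log2 difference. The median over them was 0.03 and the mean -0.04, and camera, which tests for a shared direction, gave an adjusted p = 0.814 (adjusted p = 0.905 with an estimated correlation).

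**Figure D1:**
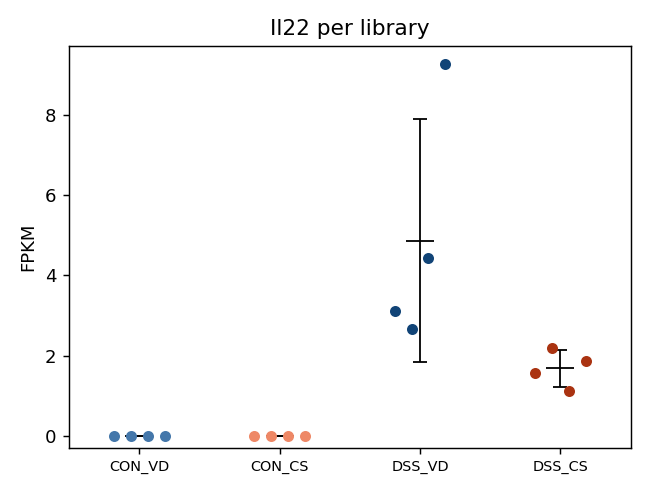
FPKM of Il22 in each library (points), with the mean and SD of each group (bars, n = 4). It is listed at 0 in all 8 water libraries. Its DSS_VD and DSS_CS values do not overlap, as for 22.5% of the genes tested between these groups.

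Matrix and matrix remodelling genes were higher in DSS_CS, with 10 of 14 past the threshold and none lower (13 adjusted over the list alone; camera adjusted p = 2.88e-07, adjusted p = 0.484 with an estimated correlation). Lox, a collagen cross-linking enzyme, went from 12.9 ± 3.42 to 32.7 ± 2.48 FPKM, the matrix glycoprotein Tnc from 41.4 ± 8.10 to 122 ± 39.9 and the metalloproteinase inhibitor Timp1 from 51.4 ± 12.5 to 147 ± 45.4. Of 16 cytokine and chemokine genes 6 were higher, including Ccl3 (log2 2.24 ± 0.30) and the interleukin-6 family cytokine Osm (2.22 ± 0.29), and Nos2 was lower (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.74e-04, adjusted p = 0.484 with an estimated correlation). Of 10 neutrophil markers 5 were higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0535, adjusted p = 0.547 with an estimated correlation). The lower ones were Ly6g, named here after its values were seen, and Ltf, which encodes the iron-binding lactoferrin, at 29.7 ± 14.7 against 3.18 ± 2.44. The score of the neutrophil list gave an exact permutation p = 0.0857. Trem1, an activating receptor of neutrophils and monocytes, rose by 2.34 ± 0.46, and Wfdc12, a whey acidic protein family member, by 2.51 ± 0.55. Gbp2 and Cxcl9, both induced by interferon, were the 2 of 19 interferon-stimulated genes that fell (log2 -1.15 ± 0.30 and -1.69 ± 0.46), while Irgm1 did not pass (adjusted p = 0.0595). Of the 19, 7 were lower adjusted over the list alone (camera adjusted p = 4.22e-06, adjusted p = 0.493 with an estimated correlation). None of 15 cell cycle genes passed, over all genes or adjusted over the list alone, although camera placed them lower (adjusted p = 3.05e-04, adjusted p = 0.519 with an estimated correlation). Mki67 was at 12.2 ± 2.73 and 7.87 ± 2.30 FPKM (adjusted p = 0.0914), Aurka at 5.65 ± 1.10 and 3.76 ± 0.948 and Birc5 at 8.09 ± 2.56 and 4.77 ± 1.92. Fatty acid oxidation genes had 3 of 14 lower, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00531, adjusted p = 0.484 with an estimated correlation). None of 10 MHC class II genes passed, over all genes or adjusted over the list alone. Camera placed them lower (adjusted p = 0.0148, adjusted p = 0.547 with an estimated correlation).

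Markers of other tissues moved with the same groups. Tubb3, Vip and Nos1 of the enteric neuron list were higher, 3 of 10 (9 adjusted over the list alone; camera adjusted p = 2.16e-04, adjusted p = 0.493 with an estimated correlation). Vip was at 30.0 ± 7.005 against 73.3 ± 23.3. Hemoglobin and other erythrocyte genes were higher, 3 of 5 (5 adjusted over the list alone; camera adjusted p = 0.00448, adjusted p = 0.493 with an estimated correlation). Hba-a2 was at 66.1 ± 43.4 against 898 ± 754. Cfd, an adipocyte-secreted complement factor, was at 3.62 ± 6.04 against 40.1 ± 42.9, and 2 of 6 adipose markers were higher (4 adjusted over the list alone; camera adjusted p = 0.0202, adjusted p = 0.493 with an estimated correlation). None of 10 smooth muscle genes passed, over all genes or adjusted over the list alone, although their median log2 difference was 0.65 and camera placed them higher (adjusted p = 0.00531, adjusted p = 0.547 with an estimated correlation). Exact permutation tests of the list scores gave p = 0.0571 for erythrocyte, 0.0571 for smooth muscle and 0.0286 for adipose markers. The prostate secretory gene Pbsn, picked after its values were seen, was at 128 FPKM in DSS_CS replicate 3 and 1355 in DSS_CS replicate 4. These libraries also had the highest erythrocyte scores, 10.04 and 9.60.

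The number of genes past the threshold under DSS rested on single libraries, with 0 without DSS_VD replicate 1 (4264 at an unadjusted limma p under 0.05), 51 without DSS_VD replicate 2, 604 without DSS_VD replicate 4, and 57, 1 and 639 without DSS_CS replicates 2, 3 and 4. It was 3 with no filter, 3855 in 1 fit on all 4 groups, and 6 without the 2 DSS_CS libraries with prostate genes.

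**Figure D2:**
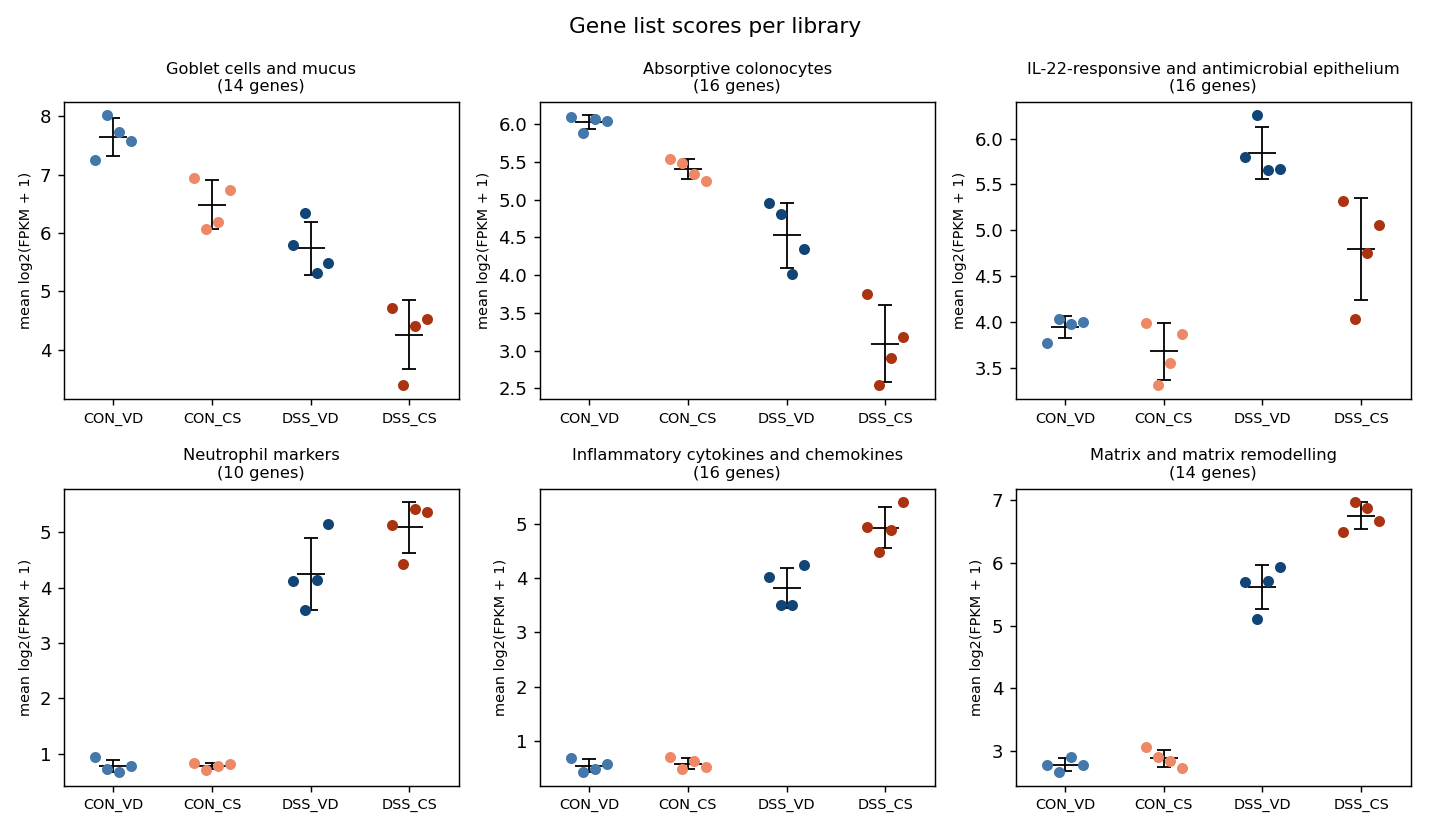
Mean log2(FPKM + 1) of 6 gene lists in each library (points), with the mean and SD of each group (bars, n = 4); each panel has its own vertical range. Goblet and colonocyte scores of the 4 DSS_CS libraries lie below those of the 4 DSS_VD libraries, with an exact permutation p = 0.0286 for each, the smallest possible.

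Without DSS, the largest fold changes of named genes between the delivery groups were losses in CS mice. Ang4, an antibacterial angiogenin of Paneth and goblet cells (ENSMUSG00000060615, chromosome 14, 51763878 to 51773590), was at 505 ± 542 FPKM in CON_VD and 1.04 ± 0.957 in CON_CS, and fell by 7.33 ± 0.78 (adjusted p = 0.0187). Mptx1 (ENSMUSG00000026531, chromosome 1, 174330518 to 174332873) and Mptx2 (ENSMUSG00000079180, chromosome 1, 173274382 to 173277777), which encode mucosal pentraxins, went from 400.4 ± 313 to 6.49 ± 1.06 and from 465 ± 397 to 8.65 ± 2.57. The sodium-hydrogen exchanger Slc9a3, the dipeptidase Dpep1 and the steroid enzyme gene Hsd3b3 fell by 3.10 ± 0.40, 2.37 ± 0.36 and 1.64 ± 0.20. The largest rises were smaller, with Anxa8 at 5.97 ± 3.32 against 31.7 ± 8.49 FPKM (log2 2.31 ± 0.33, adjusted p = 0.0333), the retinaldehyde dehydrogenase Aldh1a3 at 2.21 ± 0.460 against 12.1 ± 5.09, and Itpripl2, Cd55 and Ctnnal1 higher by 0.997 ± 0.15, 0.94 ± 0.14 and 0.83 ± 0.12. In all, 54 of 13275 genes passed, 24 higher and 30 lower in CON_CS.

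B cell and plasma cell genes were lower in CON_CS as a list, with Mzb1, a chaperone of antibody-secreting cells, past the threshold as 1 of 8 (5 adjusted over the list alone; camera adjusted p = 1.29e-06, adjusted p = 0.224 with an estimated correlation). Mzb1 was at 13.4 ± 3.999 against 3.34 ± 1.81 FPKM. The kappa light chain Igkc was at 1942 ± 404 against 443 ± 378 and the joining chain Jchain at 223 ± 40.0 against 52.6 ± 46.7, with adjusted p of 0.0640 and 0.0707. Immunoglobulin genes held 1.74% to 2.36% of FPKM in the CON_VD libraries and 0.285% to 1.47% in the CON_CS libraries, with the 1.47% in replicate 2 and at most 0.353% in the other 3. CON_VD replicate 1 had a higher score of B cell and plasma cell markers, a mean log2(FPKM + 1) of 4.61 against 3.39 to 3.42 in the other 3 CON_VD libraries. Its scores of T cell markers (1.21 against 0.371 to 0.442), MHC class II presentation (4.49 against 2.96 to 3.10) and interferon-stimulated genes (4.24 against 1.69 to 2.72) were also higher. Over the alternatives run with the preset correlation, camera placed the B cell and plasma cell markers lower with an adjusted p from 4.63e-11 to 6.17e-04, and of 8.17e-06 without CON_VD replicate 1. The adjusted p of Mzb1 ranged from 0.0122 to 0.148, and its call was lost in 13 of 19 alternatives, among them leaving out CON_VD replicate 1, 2 or 3 or CON_CS replicate 1, 3 or 4. The prostate gene Pbsn was at 185 FPKM in CON_CS replicate 1. Of the goblet list, Ang4 was the 1 of 14 that passed (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.75e-04, adjusted p = 0.277 with an estimated correlation). Clca1 was at 1845 ± 917 against 690.3 ± 138 and Fcgbp at 269.8 ± 93.6 against 141 ± 34.4. Slc9a3 and Aqp8 were the 2 of 16 colonocyte genes that fell, Aqp8 from 345 ± 63.2 to 164 ± 32.5 (5 adjusted over the list alone; camera adjusted p = 2.75e-04, adjusted p = 0.124 with an estimated correlation), and Guca2a was at 992 ± 352 against 364 ± 159.

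In 6 further lists camera gave a call although no member passed over all genes. Cell cycle genes were higher in CON_CS, 7 of 15 adjusted over the list alone (camera adjusted p = 1.66e-05, adjusted p = 0.459 with an estimated correlation). Mki67 was at 11.8 ± 3.97 against 22.1 ± 5.17, Top2a at 8.83 ± 4.40 against 17.8 ± 4.09 and Ccnb1 at 6.48 ± 0.352 against 10.3 ± 1.96. CON_VD replicate 4 had a cell cycle score of 3.38, within the 3.15 to 3.81 of the CON_CS libraries. The other CON_VD libraries scored 2.72 to 2.87. Unfolded protein response genes were lower, 4 of 10 adjusted over the list alone (camera adjusted p = 1.66e-05, adjusted p = 0.277 with an estimated correlation). Dnajb9 was at 21.9 ± 1.82 against 14.9 ± 1.59, Ddit3 at 11.7 ± 2.39 against 7.43 ± 0.629 and Xbp1 at 68.0 ± 2.86 against 54.2 ± 3.71. Enteroendocrine genes were lower, 4 of 9 adjusted over the list alone (camera adjusted p = 6.43e-04, adjusted p = 0.200 with an estimated correlation). The peptide hormone gene Sst was at 5.84 ± 2.36 against 2.06 ± 0.456, the peptide hormone gene Insl5 at 131 ± 16.1 against 86.6 ± 12.7 and the granule protein gene Chga at 18.3 ± 2.69 against 12.8 ± 1.51. Erythrocyte genes were lower, 4 of 4 adjusted over the list alone (camera adjusted p = 2.75e-04, adjusted p = 0.277 with an estimated correlation), opposite to their direction under DSS. Enteric neuron genes were lower, 2 of 4 adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.277 with an estimated correlation). Tubb3 was at 3.13 ± 0.450 against 1.68 ± 0.481 and Uchl1 at 5.67 ± 1.55 against 3.15 ± 0.417. Fatty acid oxidation genes were lower, 1 of 15 adjusted over the list alone (camera adjusted p = 0.0394, adjusted p = 0.551 with an estimated correlation). Beside them, 3 of 4 adipose markers had negative log2 differences, with none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.126, adjusted p = 0.587 with an estimated correlation). CON_VD replicate 3 had an adipose score, a mean log2(FPKM + 1), of 3.54, against 0.842 to 1.97 in the other CON_VD and 0.765 to 1.39 in the CON_CS libraries. Its fatty acid oxidation score was 4.16, against 3.87 to 4.06 and 3.82 to 3.96. For the 15 junction genes the median and mean log2 difference were both 0.01 while camera pointed lower, with an adjusted p of 0.897.

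Il22 and Il17a were listed at 0 in all 8 water libraries, and Il23r, Ifng and Tbx21 had means of at most 0.143 FPKM. The water result also rested on single libraries, with 0 genes without CON_VD replicate 3 (1875 at an unadjusted limma p under 0.05), 12 and 275 without CON_VD replicates 1 and 4, and 15, 1 and 1 without CON_CS replicates 1, 3 and 4. It was 3 with no filter and 1405 with library weights, 858 higher and 547 lower, and on the TPM scale 27 genes were higher and 18 lower. Where a change of at least 2-fold was required, 7 were higher and 19 lower. Without CON_CS replicate 2, the numbers were 14 higher and 57 lower.

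**Figure D3:**
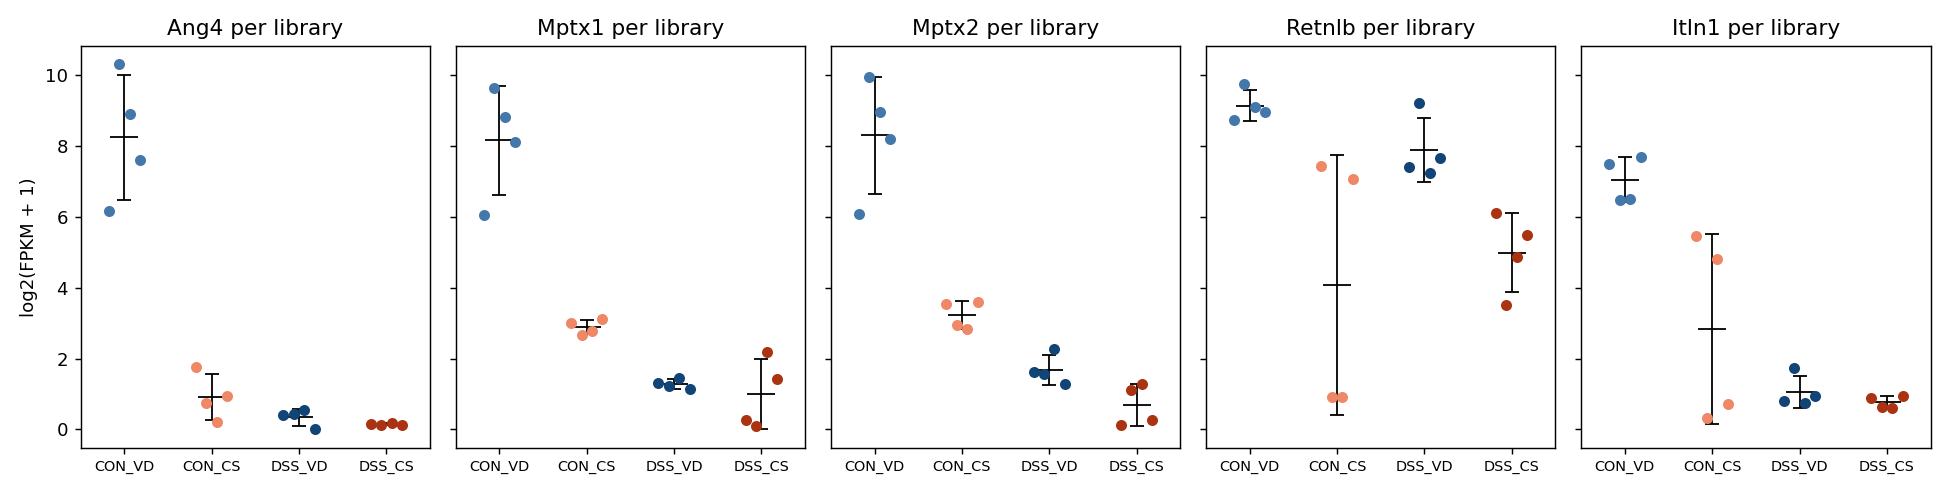
log2(FPKM + 1) of 5 genes in each library (points), with the mean and SD of each group (bars, n = 4). In each panel the 4 CON_VD libraries lie above the 4 CON_CS libraries; Retnlb and Itln1 were added after their values were seen and did not pass over all genes.

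DSS changed the colon of VD mice widely, with gains of neutrophil, cytokine and matrix genes and losses of epithelial genes. S100a9, a calcium-binding alarmin of neutrophils (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), went from 0.0486 ± 0.0698 FPKM in CON_VD to 174 ± 121 in DSS_VD, a log2 rise of 7.15 ± 0.39 (adjusted p = 7.16e-06). Its partner S100a8 went from 0.0733 ± 0.121 to 89.7 ± 57.5. Clca4b (ENSMUSG00000074195, chromosome 3, 144910921 to 144932529) rose from 6.28 ± 4.26 to 1061 ± 356 FPKM, and the stromal metalloproteinase Mmp3 from 1.17 ± 0.847 to 174 ± 30.5. Ang4, Mptx1, Mptx2 and the lectin Itln1 fell by 7.91 ± 0.73, 6.88 ± 0.63, 6.62 ± 0.70 and 5.99 ± 0.33. In all, 5704 of 13933 genes passed, 3340 higher and 2364 lower under DSS.

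All 16 cytokine and chemokine genes rose in VD mice, among them Nos2 (log2 5.37 ± 0.30), the neutrophil attractant Cxcl5 (5.32 ± 0.34) and Il11 (5.06 ± 0.35). Adjusted over the list alone the count was also 16 (camera adjusted p = 1.11e-09, adjusted p = 0.203 with an estimated correlation). All 14 matrix genes rose, with Timp1 at 2.15 ± 0.556 against 51.4 ± 12.5 and Mmp10 at 0.438 ± 0.142 against 63.2 ± 23.6 (14 adjusted over the list alone; camera adjusted p = 2.99e-09, adjusted p = 0.203 with an estimated correlation). All 8 neutrophil markers rose, Ltf by 4.73 ± 0.31 (8 adjusted over the list alone; camera adjusted p = 7.23e-06, adjusted p = 0.203 with an estimated correlation). All 14 monocyte and macrophage markers rose, such as the chemokine receptor Ccr2 (2.36 ± 0.20), Itgam (2.49 ± 0.30) and the Fc receptor Fcgr1 (2.27 ± 0.30). The count was 14 adjusted over the list alone (camera adjusted p = 2.28e-06, adjusted p = 0.261 with an estimated correlation). Of 11 T cell markers 11 rose, the regulatory T cell factor Foxp3 by 1.15 ± 0.11, Cd4 by 2.17 ± 0.23 and Ctla4 by 1.998 ± 0.23 (11 adjusted over the list alone; camera adjusted p = 1.19e-05, adjusted p = 0.261 with an estimated correlation). Members under 1 FPKM in every CON_VD library were tested only where all 4 DSS_VD libraries reached 1 FPKM, so such members could only rise. Over the 8 water libraries the filter passed 4 of 18 cytokine, 1 of 13 neutrophil and 2 of 12 T cell genes. Beside these groups, 4 of 4 erythrocyte genes rose (4 adjusted over the list alone; camera adjusted p = 0.0607, adjusted p = 0.441 with an estimated correlation), and of 6 adipose markers Lpl rose (1 adjusted over the list alone; camera adjusted p = 0.670, adjusted p = 0.866 with an estimated correlation). Plet1, the acute phase gene Saa3 and the protease inhibitor Serpina3n were also among the largest rises, by 6.34 ± 0.31, 6.02 ± 0.36 and 5.83 ± 0.41.

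On the epithelial side, 12 of 14 goblet genes fell in VD mice, such as Atoh1, the secretory lineage factor, from 22.2 ± 1.51 to 3.74 ± 1.76 FPKM, and Ern2 from 19.8 ± 5.35 to 4.26 ± 1.25 (12 adjusted over the list alone; camera adjusted p = 8.05e-06, adjusted p = 0.261 with an estimated correlation). Of 16 colonocyte genes 10 fell, including Car2 (-2.50 ± 0.15), Slc26a3 (-3.34 ± 0.29) and Guca2a (-3.39 ± 0.43). The count was 11 adjusted over the list alone (camera adjusted p = 3.28e-05, adjusted p = 0.203 with an estimated correlation). Beside these groups, the mean log2(FPKM + 1) of the 10 pan-epithelial genes was 7.39 to 7.57 in the CON_VD libraries and 6.04 to 7.13 in the DSS_VD libraries, with means of 7.49 and 6.49 (exact permutation p = 0.0286, the smallest possible). The median log2 differences of the goblet and colonocyte lists were -1.58 and -1.37. Xenobiotic metabolism genes had 10 of 12 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 7.2e-05, adjusted p = 0.203 with an estimated correlation), with the sulfotransferase Sult1a1 at 185 ± 44.0 against 6.43 ± 1.94 and the glutathione transferases Gstm3 and Gstm1 lower by a log2 of -4.13 ± 0.22 and -2.61 ± 0.17. The hydroxyacid oxidase Hao2 and the gluconeogenic enzyme Pck1 fell by 4.44 ± 0.22 and 4.28 ± 0.17. Il22 was listed at 0 in the CON_VD libraries and at 2.67 to 9.27 FPKM in DSS_VD (adjusted p = 2.22e-04). With a filter of mean FPKM of at least 5, 3208 genes passed; no single library moved the count by over 1.5 times.

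In CS mice DSS changed 8666 of 14372 genes, with 4937 higher and 3729 lower. S100a9 went from 0.0805 ± 0.161 FPKM in CON_CS to 628 ± 131 in DSS_CS, a log2 rise of 9.17 ± 0.17 (adjusted p = 2.36e-08), S100a8 from 0.171 ± 0.185 to 272 ± 67.9 and Mmp3 from 0.708 ± 0.0913 to 328 ± 119. Slc26a3 went from 94.9 ± 22.2 to 1.22 ± 1.05 and Hsd11b2, the glucocorticoid-inactivating enzyme of mineralocorticoid target epithelia, from 115 ± 7.80 to 2.17 ± 1.79. The kallikrein Klk1, Hao2, Gsdmc3, Sycn and Selenbp1 fell by 5.23 ± 0.40, 5.55 ± 0.33, 5.06 ± 0.68, 5.03 ± 0.51 and 4.78 ± 0.28. Saa3, Serpina3n, Mmp10 and the beta-globin Hbb-bt rose by 7.68 ± 0.30, 7.20 ± 0.21, 6.86 ± 0.22 and 6.96 ± 0.71.

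In CS mice, all 14 matrix genes rose, such as Lox (3.73 ± 0.09) and the collagenase Mmp13 (6.20 ± 0.16). The count was 14 adjusted over the list alone (camera adjusted p = 1.12e-07, adjusted p = 0.236 with an estimated correlation). All 16 cytokine genes rose, with Cxcl5, Il1b and Ccl3 up by 6.33 ± 0.14, 6.56 ± 0.28 and 4.54 ± 0.22 (16 adjusted over the list alone; camera adjusted p = 1.79e-07, adjusted p = 0.236 with an estimated correlation). Neutrophil markers had 8 of 9 higher, among them the receptor Csf3r (4.72 ± 0.09). The count was 8 adjusted over the list alone (camera adjusted p = 5.66e-05, adjusted p = 0.263 with an estimated correlation). All 14 monocyte and macrophage markers rose, with the complement genes C1qa, C1qb and C1qc up by 3.09 ± 0.13, 2.96 ± 0.14 and 2.89 ± 0.13 (14 adjusted over the list alone; camera adjusted p = 8.69e-07, adjusted p = 0.236 with an estimated correlation). All 12 B cell and plasma cell genes rose, including the B cell receptor parts Cd79a (4.84 ± 0.25) and Cd79b (4.19 ± 0.17) and the B lineage factor Pax5 (2.15 ± 0.09). The count was 12 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.262 with an estimated correlation). As in VD mice, members under 1 FPKM in every water library were tested only where all 4 DSS libraries reached 1 FPKM. Beside these groups, 5 of 5 erythrocyte genes and 6 of 6 adipose markers rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00709 and 0.0126; adjusted p = 0.329 and 0.329 with an estimated correlation).

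Colonocyte genes had 14 of 15 lower in CS mice, among them the monocarboxylate transporter Slc16a1 (-1.48 ± 0.08) and Scnn1a (-2.11 ± 0.15). The count was 14 adjusted over the list alone (camera adjusted p = 1.81e-06, adjusted p = 0.236 with an estimated correlation). Goblet genes had 12 of 13 lower, with Atoh1, Ern2 and Clca1 down to 0.896 ± 0.512, 1.58 ± 0.599 and 114 ± 32.3 FPKM (12 adjusted over the list alone; camera adjusted p = 1.45e-05, adjusted p = 0.297 with an estimated correlation). The pan-epithelial score moved with both groups and ranged from 7.38 to 7.56 in the CON_CS libraries and from 4.57 to 6.20 in the DSS_CS libraries, a difference of -2.17 (exact permutation p = 0.0286, the smallest possible). The median log2 differences were -2.11 for the colonocyte and -2.51 for the goblet list. Xenobiotic metabolism genes had 11 of 13 lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p = 2.82e-04, adjusted p = 0.236 with an estimated correlation), with Gstm3, Sult1a1 and Gstm1 at -4.40 ± 0.20, -4.15 ± 0.24 and -2.11 ± 0.18. Il22 was listed at 0 in CON_CS and at 1.11 to 2.18 FPKM in DSS_CS (adjusted p = 2.01e-05). The count was 4910 with a filter of mean FPKM of at least 5, and 5217 without the 3 libraries with prostate genes. In the latter fit 2 DSS_CS libraries remained, so genes under 1 FPKM in every CON_CS library missed the filter.

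The responses of VD and CS mice to DSS overlapped. Of 13632 genes tested in both, 2736 were higher under DSS in both and 1890 lower in both, where independent lists would share 1066 and 617, and 46 passed in opposite directions. The comparisons share no library. Fold changes correlated across genes with a Spearman rho of 0.79, a description in which genes are not independent replicates. Among the 4626 genes shared in direction, 74.5% had the larger change in CS mice. With a filter of mean FPKM of at least 5, 2511 genes were shared. For the differences between delivery modes, 5 genes were shared in direction between water and DSS, 1 higher and 4 lower, where independent lists would share 1.55 and 1.54, 4 passed in opposite directions, and rho was -0.02.

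**Figure D4:**
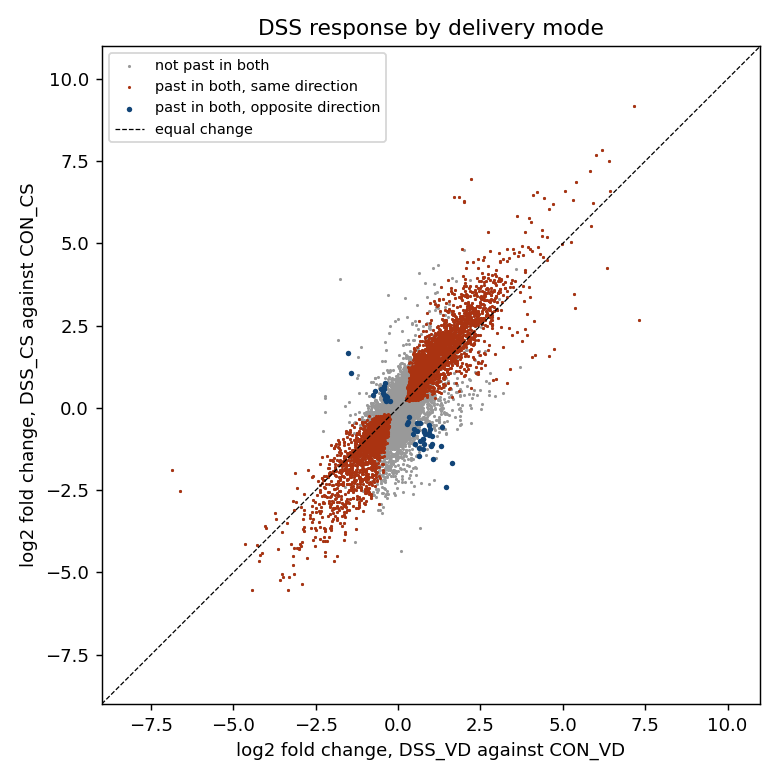
Log2 fold change under DSS in VD mice (horizontal axis) against that in CS mice (vertical axis) for 13632 genes (points). Genes past the threshold in both with 1 direction (4626) and with opposite directions (46) are coloured, and the dashed line marks equal change.

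The interaction tested whether the DSS response itself differed with delivery. Its fit assumed 1 spread per gene for water and DSS libraries together, which the fits of CS against VD did not. With 1 fit on all 4 groups, CS against VD under DSS gave 3855 genes, against 1923 on its own 8 libraries. The interaction count is therefore not directly comparable with the 1923. With the preset correlation, camera gave a call for 17 lists. It placed the response of cytokine, matrix, neuronal and erythrocyte lists higher in CS mice and that of cell cycle, junction and colonocyte lists lower, with 4 to 7 members of each past the threshold in that direction. None of these 7 calls held with an estimated correlation (adjusted p = 0.407 for each). Clca4b rose less in CS mice, from 38.4 ± 20.1 to 246 ± 118 FPKM against 6.28 ± 4.26 to 1061 ± 356 in VD mice (interaction log2 -4.64 ± 0.70, adjusted p = 0.00473). In all, 2015 of 15233 genes passed, 1017 with a more positive and 998 with a more negative response in CS mice. This balance depended on the setting, with 255 more positive and 566 more negative where a change of at least 2-fold was required, and 454 and 183 without the libraries with prostate genes. Of the 1820 measured in both DSS comparisons, 843 passed in CS mice alone, 209 in VD mice alone, 660 in both with a larger change in CS mice, 47 in both with a larger change in VD mice, 46 in opposite directions and 15 in neither. Over all tested genes, DSS calls also numbered more in CS mice, 8666 against 5704 in VD mice. The larger number in CS mice alone is thus not particular to the interaction genes. Among the most positive interactions were those of Ang4 (7.13 ± 0.86) and Mptx1 (4.98 ± 0.83), which were already low in CON_CS. Those of Cfd, Hba-a1, Hba-a2, Hbb-bs and Hbb-bt lay between 4.25 and 5.68. The most negative included S100g, Dmbt1, Abcg5, Tmem45b, Aldh1a3 and Ifit1bl1, with log2 of -4.30 ± 0.77, -3.33 ± 0.42, -3.29 ± 0.69, -3.09 ± 0.70, -3.01 ± 0.51 and -3.00 ± 0.61.

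Cell cycle genes had 6 of 15 with a more negative response in CS mice, Mki67, Top2a and Aurka by a log2 of -1.47 ± 0.33, -1.54 ± 0.39 and -1.03 ± 0.28 (12 adjusted over the list alone; camera adjusted p = 3.2e-06, adjusted p = 0.407 with an estimated correlation). Mki67 went from 22.1 ± 5.17 to 7.87 ± 2.30 in CS mice and from 11.8 ± 3.97 to 12.2 ± 2.73 in VD mice. Junction genes had 7 of 16 more negative, such as Cldn8 (-2.50 ± 0.44) and Tjp3 (-1.52 ± 0.42). The count was 12 adjusted over the list alone (camera adjusted p = 1.58e-05, adjusted p = 0.407 with an estimated correlation). Colonocyte genes had 4 of 16 more negative, including Slc26a3 (-2.18 ± 0.48), Scnn1b (-1.20 ± 0.31) and Ceacam20 (-2.001 ± 0.56), with 7 more negative and 1 more positive adjusted over the list alone (camera adjusted p = 0.00453, adjusted p = 0.407 with an estimated correlation). Goblet genes had Muc13, Atoh1 and Ern2 more negative and Ang4 more positive of 14 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00478, adjusted p = 0.504 with an estimated correlation), and IL-22-responsive genes had 8 of 16 more negative and 2 more positive (9 and 3 adjusted over the list alone; camera adjusted p = 0.00914, adjusted p = 0.407 with an estimated correlation). Beside these epithelial groups, the pan-epithelial score went from a mean of 7.46 to 5.29 under DSS in CS mice and from 7.49 to 6.49 in VD mice. The difference between these responses was -1.17, with an exact permutation p = 0.0706 in a test added after the values were seen. That p does not test the interaction alone, since a delivery difference under DSS only could also lower it. The median interaction was -1.06 for junction, -0.92 for colonocyte and -1.08 for goblet genes. Gbp2 was the 1 of 19 interferon-stimulated genes that passed (-2.58 ± 0.55; 1 adjusted over the list alone; camera adjusted p = 6.83e-04, adjusted p = 0.534 with an estimated correlation), while Gbp3 and Cxcl9 had adjusted p of 0.0635 and 0.0730.

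Matrix genes had 6 of 14 with a more positive response, such as Lox (1.12 ± 0.20), Timp1 (1.61 ± 0.30) and Mmp13 (1.4996 ± 0.33). The count was 12 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.407 with an estimated correlation). Cytokine genes had 6 of 16 more positive and Nos2 more negative (9 and 1 adjusted over the list alone; camera adjusted p = 2.47e-04, adjusted p = 0.407 with an estimated correlation), with Osm, Ccl4 and Ccl3 at 2.36 ± 0.33, 2.88 ± 0.42 and 2.12 ± 0.35. Enteric neuron genes had 5 of 10 more positive, Tubb3, Vip and Uchl1 among them (1.99 ± 0.29, 1.67 ± 0.34 and 1.61 ± 0.34). The count was 9 adjusted over the list alone (camera adjusted p = 1.46e-05, adjusted p = 0.407 with an estimated correlation). All 5 erythrocyte genes were more positive (5 adjusted over the list alone; camera adjusted p = 1.25e-04, adjusted p = 0.407 with an estimated correlation). Of 6 adipose markers Cfd and Car3 were more positive (5 adjusted over the list alone; camera adjusted p = 0.00541, adjusted p = 0.407 with an estimated correlation), and of 10 neutrophil markers 5 were more positive and 2 more negative (7 and 2 adjusted over the list alone; camera adjusted p = 0.0173, adjusted p = 0.504 with an estimated correlation). Il22 did not pass (adjusted p = 0.0538).

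The interaction count was 1096, 1238, 1311, 1242, 1056 and 1181 without CON_VD replicate 3, CON_CS replicates 3 and 4, DSS_VD replicate 2, and DSS_CS replicates 2 and 3. It was 1042 with no filter, 1310 with the stricter filter, 637 without the libraries with prostate genes and 976 without those with the most adipose RNA, and on the TPM scale 588 genes were more positive and 924 more negative.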

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

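Of the tests in this part, those on prostate dilution, goblet cell number, paralogs, position along the colon, other prostate genes and carry-over of reads were chosen after the result was seen; the splits of the libraries and the epithelial share were not.

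In each comparison the real grouping gave more genes than every other split tried. With 35 splits, 1 of 35 is the smallest share possible. Libraries of a group may also share a litter, so chance is not excluded. For CS against VD under DSS 1 of 35 splits of the 8 libraries, the real one, gave as many genes, with 1923 against at most 2 in the others. The values were 54 against 2 for CS against VD under water, 5704 against 3 for DSS in VD mice and 8666 against 1 for DSS in CS mice, again 1 of 35 each. For the interaction 1 of 100 drawn splits gave as many, with 2015 against 1111. The splits with 1111, 1001 and 570 genes relabelled 4, 4 and 2 water libraries and no DSS library. They kept the delivery groups under DSS, and the next highest split gave 3. Most splits thus also broke up a delivery difference under DSS alone, so they cannot test the interaction by itself.

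Goblet and colonocyte genes were lower in DSS_CS than in DSS_VD. Prostate RNA diluting DSS_CS replicates 3 and 4 is argued against, since over 30 members of both lists the median log2 difference was -1.36 with all libraries and -1.52 without those 2. A smaller share of epithelial RNA in DSS_CS may account for both groups and stays open, since pan-epithelial genes differed by -1.20 (exact permutation p = 0.0857). Relative to them, the goblet score differed by -0.28 (exact permutation p = 0.314) and the colonocyte score by -0.24 (exact permutation p = 0.543), which cannot be told apart from a loss of epithelium with 4 libraries a group. An effect of delivery itself, litter and outbred background also stay open and were not tested.

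Ang4, Mptx1 and Mptx2 were lower in CON_CS than in CON_VD, and Retnlb and Itln1, picked after their values were seen, had ranges apart in the same direction (exact permutation p = 0.0286 each, the smallest possible) but did not pass over all genes (limma adjusted p = 0.147 and 0.125). Group ranges were apart for 10.7% of all genes tested between CON_CS and CON_VD. The median log2 difference of the 5 was -5.07, and that of 12 other goblet genes -0.29 (SD 0.52, from -1.31 to 0.52). The 5 were picked for their falls in these libraries, so a gap was likely in advance and is no independent support. The 12 belong to the goblet list fixed before the data were examined, and the largest fall among them was -1.31. Those 12 values, and not the gap, argue against fewer goblet cells as the whole cause of falls near -5.07. Reads moved between paralogs are argued against, since the summed FPKM of 5 angiogenin genes differed 142-fold and that of Mptx1 and Mptx2 57.1-fold. A more distal piece of colon stays open, since Hoxa13, Hoxb13 and Hoxd13 differed by a mean log2 of 0.0884 (95% interval -0.27 to 0.45), which does not exclude a small rise. An effect of delivery itself, litter, cage and outbred background also stay open and were not tested.

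Pbsn, Tgm4 and Defb50, secretory genes of the male tract, were high in 3 CS libraries, with Pbsn at 185 FPKM in CON_CS replicate 1, 128 in DSS_CS replicate 3 and 1355 in DSS_CS replicate 4, and at most 0.526 in each of the other 13. Reads carried over from DSS_CS replicate 4 are argued against for CON_CS replicate 1, where the ratios of the 3 genes to that library differed 12.7-fold, and stay open for DSS_CS replicate 3, where they differed 2.22-fold. Prostate tissue in the sample could be the source, but 1 of 3 further prostate genes, Msmb, had its 3 highest values in those libraries, which leaves it open. The seminal vesicle genes searched reached at most 2.10 FPKM in any library. No biological explanation was tested.

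Single libraries stood apart from the other 3 of their group, on the log2 scale, in 21 of 312 pairs of a named gene and a group with a value of at least 1 FPKM; chance flags about 1 in 20 groups, or about 16 here. Values are FPKM. In DSS_CS replicate 2 these were Aqp8 (lowest at 2.43, others 12.1 to 13.8) and Fcgbp (lowest at 10.998, others 24.8 to 25.9). In CON_CS replicate 1 this was Lox (lowest at 1.23, others 1.62 to 1.71). In DSS_CS replicate 1 these were Lox (lowest at 29.1, others 33.6 to 34.4), Aldh1a3 (highest at 73.8, others 26.2 to 31.3), Gsdmc3 (highest at 17.4, others 0.797 to 1.48), Sycn (highest at 27.9, others 4.24 to 5.79), Gbp3 (highest at 16.6, others 9.72 to 10.4) and Ceacam20 (highest at 22.1, others 6.03 to 6.91). In CON_VD replicate 3 this was Timp1 (highest at 2.98, others 1.78 to 1.95). In CON_VD replicate 1 these were Cxcl9 (highest at 3.35, others 0.203 to 0.463), Pck1 (lowest at 32.7, others 47.9 to 51.3) and Cd4 (highest at 1.63, others 0.684 to 0.780). In CON_CS replicate 2 these were Vip (highest at 11.8, others 7.21 to 7.55) and Abcg5 (highest at 19.1, others 6.01 to 7.13). In DSS_VD replicate 4 this was Vip (highest at 40.5, others 25.6 to 27.6). In CON_VD replicate 4 this was Aurka (highest at 7.82, others 4.30 to 4.71). In CON_CS replicate 3 these were Chga (highest at 15.1, others 12.0 to 12.2) and Slc16a1 (highest at 61.9, others 58.3 to 58.7). In DSS_VD replicate 3 this was Car2 (lowest at 30.7, others 43.1 to 44.3). In CON_CS replicate 4 this was Ifit1bl1 (highest at 233, others 158 to 168).

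The response to DSS differed between CS and VD mice by limma's interaction test, at an adjusted p under 0.05, for 32 named genes. On the log2 scale it was more positive in CS mice for Ang4 (7.13), Cfd (5.68), Mptx1 (4.98), Hbb-bt (4.76), Hba-a2 (4.72), Hbb-bs (4.28), Hba-a1 (4.25), Ccl4 (2.88), Osm (2.36), Ccl3 (2.12), Tubb3 (1.99), Vip (1.67), Timp1 (1.61), Uchl1 (1.61), Mmp13 (1.4996), Lox (1.12). It was more negative for Clca4b (-4.64), S100g (-4.30), Dmbt1 (-3.33), Abcg5 (-3.29), Tmem45b (-3.09), Aldh1a3 (-3.01), Ifit1bl1 (-3.00), Gbp2 (-2.58), Cldn8 (-2.50), Slc26a3 (-2.18), Ceacam20 (-2.0006), Top2a (-1.54), Tjp3 (-1.52), Mki67 (-1.47), Scnn1b (-1.20), Aurka (-1.03).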

How the results depend on the processing

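Leaving out the libraries with prostate or adipose genes was chosen after seeing the data; the other alternatives were not. No named gene reversed direction under any alternative run. Apart from leaving out single libraries, 333 of 333 values of named genes for DSS in VD mice and 361 of 361 in CS mice kept their side of the threshold, against 292 of 414 for CS against VD under DSS, 295 of 380 under water and 316 of 346 for the interaction. With single libraries left out, 224 of 224, 236 of 236, 147 of 300, 195 of 280 and 526 of 560 did, in the same order. A fit gave no value where a gene missed the filter, as genes near 0 in water did without a DSS library. S100a9 and Il22 had values in 14 and 13 alternatives for DSS in VD mice, against 18 for Mmp3. Cxcl5 and Il22 had 13 and 12 in CS mice, against 19 for Lox. Such genes were not retested without a DSS library.

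With a change of at least 2-fold required, the counts were 611 for CS against VD under DSS, 26 under water, 2252 for DSS in VD mice, 3728 in CS mice and 821 for the interaction, which follows from fewer genes being eligible. With an estimated correlation 0 gene lists passed in camera (limma) in each of the 5 comparisons, and 1, 3, 6, 3 and 1 had an unadjusted p under 0.05. For the following the cause was not tested. With no filter 3 genes passed under DSS, 3 under water and 1042 for the interaction. One fit on all 4 groups gave 3855 under DSS, and array weights gave 1405 under water. Without the libraries with prostate genes 6 genes passed under DSS, 15 under water, 5217 for DSS in CS mice (14 lists) and 637 for the interaction. For DSS in CS mice 2 DSS_CS libraries remained, so genes under 1 FPKM in every CON_CS library missed the filter. There the higher genes went from 4937 to 2802 and the lower ones from 3729 to 2415. Without the libraries with the most adipose RNA 639 passed under DSS, 0 under water (1875 at an unadjusted limma p under 0.05) and 976 for the interaction. In comparisons of 2 groups that fit left out only CON_VD replicate 3 or DSS_CS replicate 4. The prostate fit under water left out only CON_CS replicate 1. These fits repeat those with a single library left out, so they enter both tallies of named genes above. The stricter filter, which tests fewer genes, gave 3208 for DSS in VD mice, 4910 in CS mice, 1310 for the interaction and 2511 shared responses. On the TPM scale the median log2 fold change of all genes was 0.13 under DSS, 0.13 under water, 0.14 for DSS in VD mice and 0.11 in CS mice, against 0.06, 0.03, 0.06 and 0.06 on the values as deposited.

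Leaving out 1 library gave 0 to 2054 genes under DSS (0 without DSS_VD replicate 1, with 4264 at an unadjusted limma p under 0.05), 0 to 275 under water (0 without CON_VD replicate 3), 4050 to 5410 for DSS in VD mice, 6950 to 7909 in CS mice and 1056 to 2515 for the interaction.

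With the replicate number as a block 2 genes passed under DSS and 7 under water. Labels do not pair the samples, and at most 1 of 4 same-numbered pairs had deviations correlated above 0.1. Read depth is unknown, so counting error cannot be separated from the spread between samples.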

Other observations

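The lists described here were fixed before the data were examined; the members named and the heat shock genes were picked after their values were seen, and no test was added for them.

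Beyond the groups above, DSS was accompanied by lower crypt base genes, with 7 of 10 lower and 1 higher in VD mice (7 and 1 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.261 with an estimated correlation). In CS mice 7 of 11 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.00602, adjusted p = 0.263 with an estimated correlation). Ascl2, a stem cell transcription factor, and Axin2, a Wnt target, were among the lower ones in both. Enteroendocrine genes were higher, 7 of 10 in VD mice (9 adjusted over the list alone; camera adjusted p = 0.00380, adjusted p = 0.261 with an estimated correlation) and 6 of 10 in CS mice (7 adjusted over the list alone; camera adjusted p = 0.00644, adjusted p = 0.329 with an estimated correlation), with Cck, Chgb, Gcg and Tph1 in both. MHC class II genes were higher, 9 of 10 in VD mice (10 adjusted over the list alone; camera adjusted p = 2.33e-04, adjusted p = 0.290 with an estimated correlation) and 9 of 10 in CS mice (9 adjusted over the list alone; camera adjusted p = 8.09e-04, adjusted p = 0.329 with an estimated correlation). In VD mice the B cell and plasma cell score also rose. It ranged from 3.39 to 4.61 in the CON_VD libraries and from 5.64 to 6.41 in the DSS_VD libraries.

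Smooth muscle genes were lower under DSS in VD mice, 8 of 10 (9 adjusted over the list alone; camera adjusted p = 1.89e-04, adjusted p = 0.261 with an estimated correlation). In CS mice 2 of 10, Actg2 and Myh11, were lower (1 adjusted over the list alone; camera adjusted p = 0.224, adjusted p = 0.734 with an estimated correlation). The interaction had none of 10 past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.0447, adjusted p = 0.550 with an estimated correlation). Unfolded protein response genes were higher under DSS in CS mice, 8 of 10 (8 adjusted over the list alone; camera adjusted p = 0.0241, adjusted p = 0.446 with an estimated correlation). In VD mice 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.585, adjusted p = 0.821 with an estimated correlation). In the interaction Ddit3 and Atf4 were the 2 that passed, both more positive in CS mice (2 adjusted over the list alone; camera adjusted p = 0.00624, adjusted p = 0.504 with an estimated correlation).

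CON_VD replicate 4 had Hspa1a at 281 FPKM and Hspa1b at 432, while the other 15 libraries had at most 28.5 and 41.3.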
